A study of Mus musculus with 2 samples.

How the data were processed

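Total RNA from the liver of C57BL/6 mice was amplified, labelled with the dye Cy3 and hybridized to 1-colour Agilent arrays, with 1 array of a wild-type liver and 1 array of a liver from a mouse carrying Alb-Cre and a floxed-neo Snail transgene under the CAG promoter. Alb-Cre is a Cre recombinase driven by the albumin promoter, which is active in hepatocytes. The groups were taken from the genotype in the labels. The labels do not give the sex, age or diet of the animals, or say whether the sampled tissue held a tumour.

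The authors deposited scanner output of Agilent Feature Extraction 9.5.1.1, per the submitters' processing notes. Its intensity values are background-subtracted and spatially detrended within each array and were not scaled between arrays, per the file headers. Both arrays lay on 1 slide and were read in 1 scan, so there was no batch to set apart. Each array held 44397 spots, of which 43020 were not controls, and 399 of the probes were printed 10 times. The annotation in the files refers to the mouse build mm9, and coordinates are given on it.

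The authors also deposited a value table of the same arrays with 1 row for each of 39429 probes. Its scale and centring are not given in the sources used here. Set against the scanner intensity values, its columns were linear and followed their own array across probes, with a correlation of log2 values of 1.00 for each, against 0.976 between the wild-type column and the other array. Both columns had a median of 17.3 and the same sorted values to within 0.108, as after quantile normalization. The table was used as an alternative source of values.

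From the scanner files, log2 of the processed signal minus each array's 75th percentile over non-control spots was computed. That percentile was a signal of 232.7 on the wild-type array and 302.1 on the other. Control spots and the 287 non-control spots marked as outliers by the scanner software on either array were left out, and no spot was saturated. Spots of a probe were averaged on the log2 scale. A gene's value is the mean over its probes that were well above background on both arrays, by the scanner software's own call. A gene with no such probe, but with a probe well above background on 1 array, has only a bound. The bound divides the bright array's scaled signal by the higher of 2 values on the dim array, the lowest signal among spots well above background and the probe's own signal, and is written as at least N-fold. Where the probe's own signal was the higher, the quotient is the observed ratio of scaled signals and no lower limit. It is then given without the words at least. The lowest signals among spots well above background were 13.8 on the wild-type array and 12.9 on the other. Genes below background on both arrays have no fold. Probes of a gene whose log2 differences span more than 1 were counted as disagreeing.

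Probes were named by their accession through a table of RefSeq genes of the assembly GRCm38.p6, used for names only. Of the 39429 probes, 26055 (66.1%) were matched in this way, and the others kept the name in the scanner files, which can be old. This gave 31894 gene names.

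With 1 array per group there are no replicates, so no test was run and no p-value is given. Genes were counted by a fixed rule of size, at least 2-fold. The 240 probes with at least 5 usable spots that were well above background on both arrays gave a technical spread, as the median over probes of the SD of the log2 difference between single spots. It was 0.10 over all of them, 0.23 for signals under 100, 0.09 for signals from 100 to 1000 and 0.08 above 1000. Of 2277 such spots, 1 lay at least 2-fold from its probe's mean. This spread holds array noise within 1 pair of hybridizations and no difference between animals, and the number of arrays limits the precision.

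Before the data were examined, 10 gene lists for the study's question, 27 lists of other liver functions and cell types and 14 background lists were fixed, together with the rule for named genes. Each list is described by the median log2 difference of its measured members and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 libraries only. Of 1190 genes in the lists, 74 were in more than 1 list. The genes named are Snai1, the 10 genes with the largest log2 differences in each direction and the 5 with the largest bounds in each direction. RIKEN, Gm, LOC, pseudogene and accession names were passed over, which skipped 2 higher genes and 1 lower gene among the top genes. To these come 4 members of each list for the study's question, 3 of each other list and 2 of each background list, by size of difference. All erythroid and Y-linked genes were also allowed, as were Cdh1, Krt18, Afp, Pparg, Srebf1, Cd36, Col1a1, Tnf, Alb and Mki67. Members of a list with only a bound could be named with it. Not every gene that the rule allows is printed.

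Alternatives were normexp background correction with an offset of 50 in limma 3.58.1, quantile normalization, centring on the median difference, loess between the arrays, no filter or a stricter filter on dim probes, the brightest probe per gene, the authors' value table and outlier spots kept. Without a filter, probe signals under an array's floor, its lowest signal well above background, were raised to that floor. Genes under both floors then take 1 constant difference, that between the floors. Thresholds of 1.5-fold and 4-fold, random lists not matched on expression and lists without shared members were also tried. A further alternative, setting each gene against the median of the 100 genes nearest to it in mean signal, was chosen after seeing the data. Leaving out a replicate and a slide block were not possible with 1 array per group on 1 slide. Analyses ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, in R 4.3.3 and with matplotlib 3.10.9.

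The counting and list steps were tested on simulated data made from the wild-type signals, for the comparison of both libraries. Noise with an SD of 0.15 was added on the log2 scale, and the calls above background were copied from the wild-type array. All 50 genes at each simulated log2 difference of 1.5, 3, -1.5 and -3 were recovered among 15937 genes, and 0 of 15717 genes without a difference passed the 2-fold rule. With noise so small against the 2-fold rule, and under the technical spread of 0.23 at dim signals, these counts were close to fixed in advance. They check the arithmetic, and neither the filter on dim probes nor the bounds. A list shifted by 0.8 had a median of 0.82 and a percentile of 100, and 3 of 48 lists that were not shifted lay outside the central 95% of random lists.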

Results

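Gene expression in liver was measured on 1 array of a wild-type C57BL/6 mouse and 1 array of a mouse with Alb-Cre and a floxed-neo Snail transgene. The series title names steatohepatitis and liver tumours that follow forced Snail expression in hepatocytes, and the comparison asks how the 2 livers differ. On the wild-type array 21800 of 43020 non-control spots (50.7%) were well above background, and on the other array 23230 (54.0%). Of 31894 gene names, 15466 were measured on both arrays, 1393 were well above background only in the library labelled Snail, 463 only in the wild-type library, 14564 on neither, and 8 had probes seen on different arrays. All differences below are log2 differences or folds of scaled signals, the library labelled Snail against wild-type, and none has a replicate check. Signals quoted beside them are not scaled between the arrays.

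Snai1, which encodes the zinc-finger repressor Snail, was not higher in the library labelled Snail. Its single probe, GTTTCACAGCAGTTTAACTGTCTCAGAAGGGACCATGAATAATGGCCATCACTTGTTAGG, lies on chromosome 2 from 167368073 to 167368132 (mm9). Its signal was 23.2 in wild-type liver and 22.3 in the other, a log2 difference of -0.44. The technical spread of the log2 difference at such dim signals was 0.23. Neither the position of this probe relative to the coding sequence nor the content of the transgene is given in the sources used here, so the probe does not check the labels, and the second library is called the library labelled Snail throughout. Under the stricter filter on dim probes Snai1 had no value.

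In the library labelled Snail, 613 genes (3.96% of those measured on both arrays) were at least 2-fold higher and 980 (6.34%) at least 2-fold lower. The largest difference upward was that of Gsn, which encodes the actin-severing protein gelsolin, at 468.3-fold, with signals of 162.0 and 98484. It was followed by Plin4, a coat protein of lipid droplets, at 125.0-fold, Cidec, which promotes droplet fusion, at 118.1-fold, Ly6d at 111.5-fold and the desaturase Scd2 at 75.9-fold. Rad51b, Cib3, Cyp2c55, the tetraspanin Cd63 and the irisin precursor Fndc5 were between 27.0-fold and 47.5-fold higher. The largest difference downward was that of the metallothionein gene Mt2, at 159.5-fold lower. Spp2 was 54.8-fold lower, the uridine phosphorylase Upp2 52.4-fold, Plekhb1 50.8-fold, the metallothionein gene Mt1 49.4-fold, the clock-controlled transcription factor Dbp 41.8-fold, Svip 41.4-fold, Wfdc21 37.2-fold, Dntt 32.7-fold and Perp 30.2-fold.

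Larger still were some genes well above background on 1 array only. H19, an imprinted long noncoding RNA of fetal liver, was at least 2108-fold higher in the library labelled Snail, with signals of 7.74 and 37803 at its probe on chromosome 7 from 149761492 to 149761551 (mm9). A second H19 probe was not well above background on either array, at 3.17 and 3.09. Cox8b, a cytochrome c oxidase subunit of muscle and brown fat, was at least 1917-fold higher, Cyp4a12b at least 671.0-fold, Cyp4a12a at least 448.9-fold and Amn at least 163.1-fold. In the other direction Cyp3a44 was at least 179.0-fold lower, the dicarboxylate transporter Slc13a2 at least 38.8-fold and Gnat1 at least 21.3-fold. Snai2 was 23.4-fold lower by its observed signals, 288.6 in wild-type liver and 16.0 in the other. Folds of genes dim on 1 array depend on the background step: with normexp, 297 genes were at least 2-fold higher and 572 lower, and the H19 bound was 8.81 on the log2 scale against 11.04. Without a filter the H19 value was 5.28, the mean of the bound of the first probe and the difference between the floors for the second. Of 235 values of named genes 95 moved by over 1.5-fold with normexp. Under the stricter filter on dim probes the counts were 231 and 517.

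**Figure D1:**
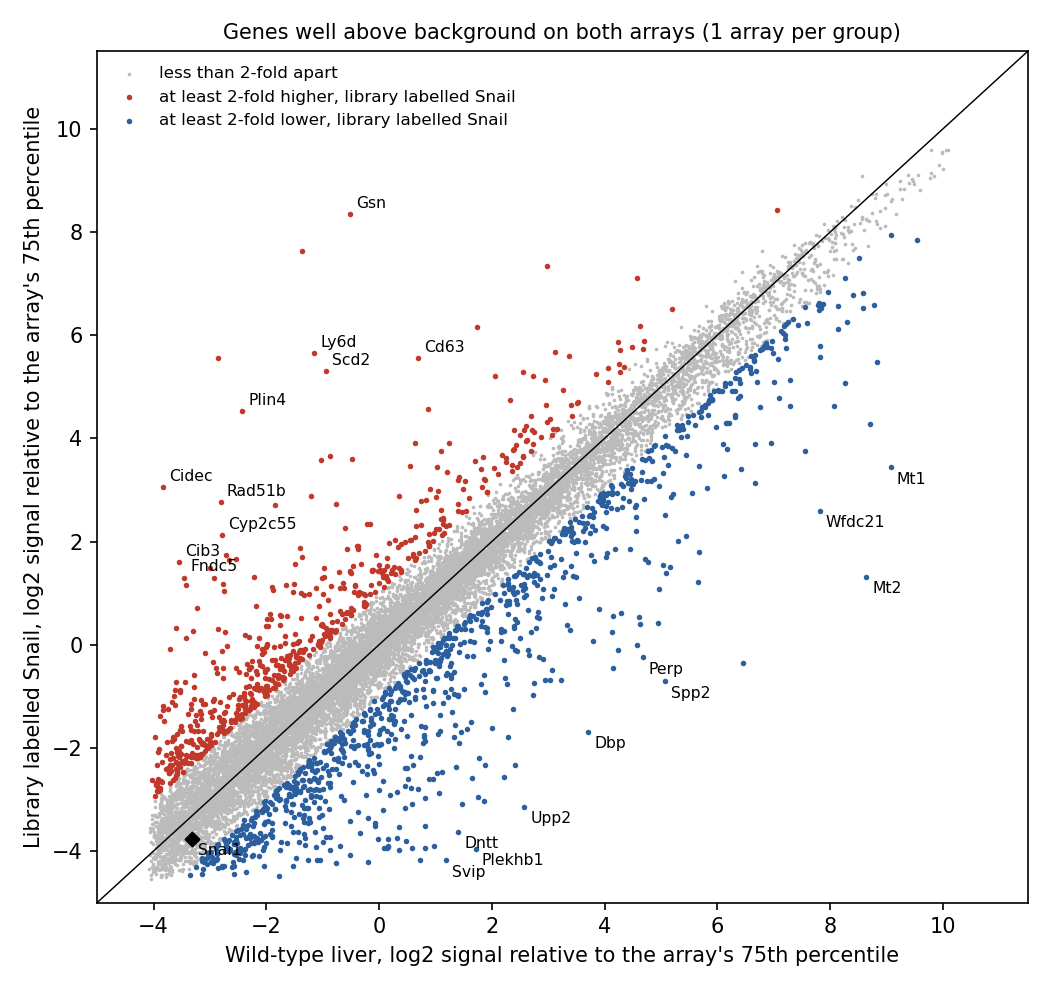
Each point is a gene well above background on both arrays, with the log2 signal relative to the array's 75th percentile in wild-type liver (x axis) and in the library labelled Snail (y axis). Red points (613) are at least 2-fold higher and blue points (980) at least 2-fold lower in the library labelled Snail, the line marks equal values, and the diamond is Snai1.

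Genes of epithelial junctions were lower in the library labelled Snail. Of 24 measured members of the adhesion and tight junction list, 11 were at least 2-fold lower and 0 at least 2-fold higher, with a median log2 difference of -0.88, below all 10000 random lists. The gap junction gene Gjb2 was 21.7-fold lower, Cldn3, a tight junction claudin, 20.1-fold, the tight junction adaptor Cgn 18.5-fold and the desmosomal plakophilin Pkp2 16.7-fold. Cdh1, which encodes E-cadherin and is a classical target of Snail repression, was 15.2-fold lower, with signals of 259.9 and 22.2. The Cdh1 log2 difference was -3.93, and -2.21 with normexp. Krt18, an epithelial keratin, was 1.77-fold lower.

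Among EMT transcription factors and mesenchymal genes, 13 were measured, 2 were at least 2-fold higher and 0 at least 2-fold lower, with a median of 0.55 at percentile 99.99. The galectin gene Lgals1 was 5.35-fold higher, S100a4 2.55-fold, the integrin gene Itga5 1.99-fold and the intermediate filament gene Vim 1.87-fold, while Snai2 had the lower value given above. Log2 differences were above 0 for 8 of the 13 measured genes and below 0 for the others. With Snai2 at its value the median was 0.36. Under the stricter filter on dim probes the median was -0.02 at percentile 66.7, and without a filter it was -0.27 at percentile 41.5, where the median of all genes was -0.47.

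Lipid genes went in different directions by list. Of 21 measured lipid droplet and lipid uptake genes, 6 were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 0.35 at percentile 99.99. Beside Plin4 and Cidec, the lipolysis inhibitor G0s2 was 7.61-fold higher, the adipogenic nuclear receptor Pparg 4.10-fold and the fatty acid transporter Cd36 1.71-fold, and the acyltransferase Mogat1 had a bound of 5.64 on the log2 scale. The triglyceride lipase Pnpla2 was 5.23-fold lower. Cidec was measured by a probe on chromosome 6 from 113374630 to 113374689 (mm9), with signals of 16.4 in wild-type liver and 2516 in the other. The wild-type signal was near the lowest signal well above background on that array, 13.8. Its second probe was well above background only in the library labelled Snail, with signals of 3.88 and 43.9. Without a filter, where the 2 probes are averaged, the Cidec log2 difference was 4.09 in place of 6.88. The wild-type signal of the second probe was raised to the floor of its array there, so 4.09 is partly a bound.

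Genes of the lipogenesis list were lower, with 6 of 22 at least 2-fold lower, 0 at least 2-fold higher and a median of -0.68, below all random lists. The desaturase Scd2, 75.9-fold higher, was placed in the tumour list and is not counted here. The carboxylase Acacb was 4.56-fold lower, Acss2 2.95-fold and Lpin1 2.72-fold, and Srebf1, which encodes the lipogenic transcription factor SREBP-1, was 1.99-fold lower. Thrsp, a regulator of lipogenesis, had a log2 difference of -1.59. In cholesterol synthesis and uptake 17 of 25 genes were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.25, below all random lists. Sqle, the squalene epoxidase, was 12.9-fold lower, Tm7sf2 5.09-fold and Idi1 4.94-fold.

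Of 29 measured genes of fatty acid oxidation and ketogenesis, 2 were at least 2-fold higher and 0 at least 2-fold lower, with a median of -0.31 at percentile 1.70. The 2 higher genes were Cpt1b, the muscle-type carnitine palmitoyltransferase, at 15.2-fold, and the pyruvate dehydrogenase kinase Pdk4, at 5.52-fold; the liver-type gene Cpt1a was 1.87-fold lower. The median of this list was within the random lists under quantile normalization, at percentile 4.09, under loess, at 6.65, in the authors' value table, at 3.77, without shared members, at 3.73, and against genes of like signal, at 5.53. Genes of cholesterol efflux and lipoproteins had a median of -0.18 at percentile 19.1, with Apoc2 2.59-fold higher and Apoa4 2.44-fold lower. Respiratory chain genes had a median of -0.01 at percentile 85.9, which was 0.15 under quantile normalization, and 0 of 31 were 2-fold apart. The member with the largest difference was Uqcrfs1, at 1.35-fold lower.

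Liver tumour and oncofetal genes were higher as a group. Of 25 measured members 8 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.61, above all random lists. Beside Ly6d, Scd2 and Cd63, the fetal albumin homologue Afp was 7.90-fold higher, with signals of 35.0 and 358.9, while the fatty acid binding protein gene Fabp5 was 11.3-fold lower. Among members seen on 1 array only, Vil1 was at least 13.5-fold higher, Igf2bp3 at least 5.32-fold and Igf2 at least 2.97-fold. Bex4 was at least 4.66-fold lower, and Akr1c18 2.63-fold lower by its observed signals. With the members seen on 1 array at their bounds the median was 0.73. A further 7 of the 39 members were below background on both arrays.

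Cell cycle genes were also higher, with 8 of 20 measured members at least 2-fold higher, 1 at least 2-fold lower and 10 more well above background only in the library labelled Snail. The mitotic genes Cdc20 and Ube2c were 9.03-fold and 5.64-fold higher, and the proliferation marker Mki67 was 2.44-fold higher. Plk1 was at least 9.33-fold higher, Kif20a at least 6.45-fold and Cenpe at least 5.10-fold, whereas Tk1 was 5.90-fold lower. The median was 0.47 at percentile 99.97, and 0.96 with bounds. It was -0.19 at percentile 27.3 under the stricter filter, which removes dim genes.

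Cholangiocyte and progenitor markers had a median of 0.23 at percentile 96.4, with Bicc1 11.2-fold and Krt23 3.92-fold higher and Alcam 6.09-fold lower, and a median of 0 with bounds. This list was above the random lists under quantile normalization, at percentile 99.71, under loess, at 99.59, in the authors' value table, at 99.35, without shared members, at 99.78, and against genes of like signal, at 99.23. Its median turned to -0.04 at percentile 52.5 with normexp, -0.03 at percentile 54.9 under the stricter filter and -0.47 at percentile 18.2 without a filter. Genes of p53 signalling and apoptosis had a median of 0.08 at percentile 80.9, and 0.02 with bounds. The cell cycle inhibitor Cdkn1a was 5.82-fold higher and Gadd45a 3.19-fold lower, beside the lower value of Perp.

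**Figure D2:**
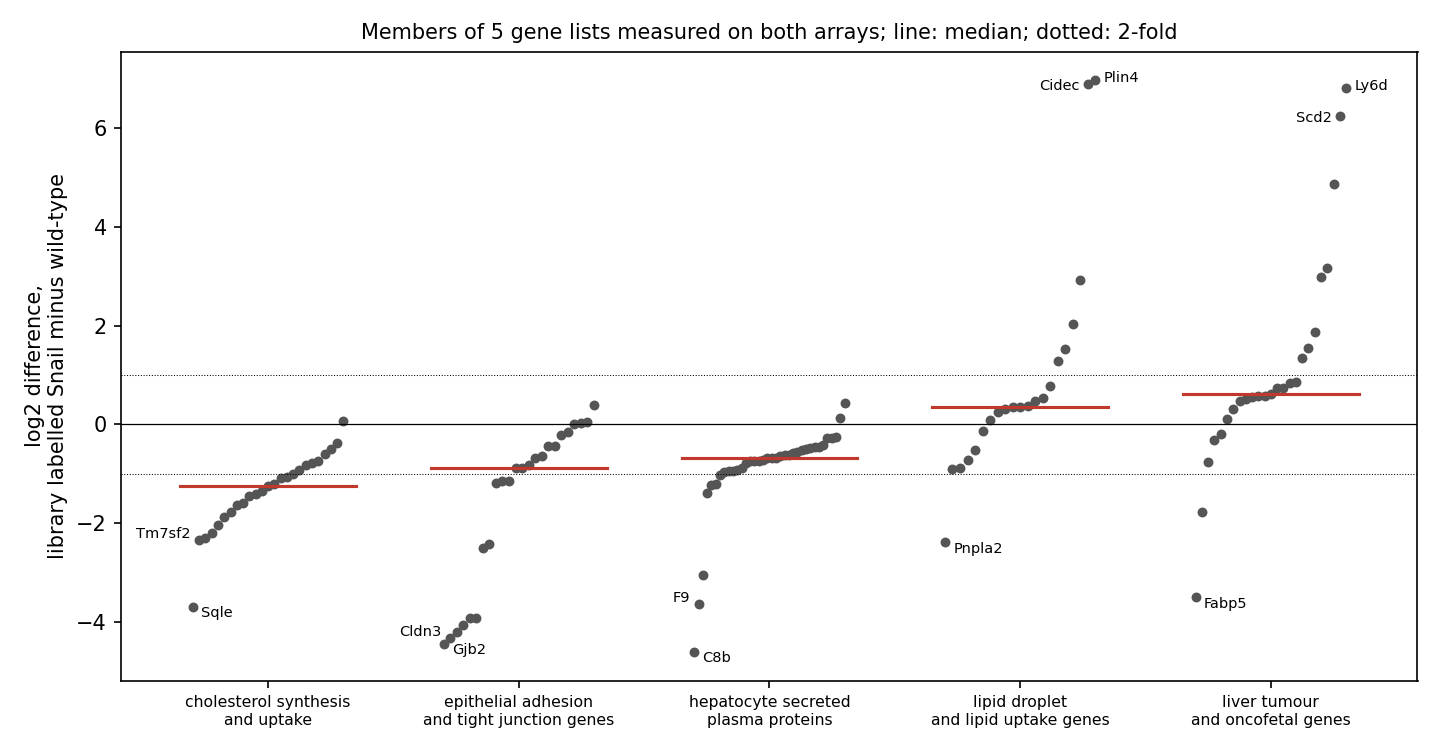
Log2 difference (y axis, library labelled Snail minus wild-type) of every gene measured on both arrays in 5 gene lists, ordered by value within each list (x axis). Red lines are list medians, -1.25 for cholesterol synthesis, -0.88 for junction genes, -0.68 for plasma proteins, 0.35 for lipid droplet genes and 0.61 for tumour genes, and dotted lines mark 2-fold.

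Inflammatory and immune gene lists went in different directions. Of 22 measured cytokine and chemokine genes 3 were at least 2-fold higher and 4 at least 2-fold lower, with a median of 0.18 at percentile 93.0. The adhesion molecule gene Vcam1 was 2.45-fold higher, Cxcl1 2.54-fold lower, Il18 2.27-fold lower and Il33 2.25-fold lower, and Tnf was not well above background on either array. Log2 differences were above 0 for 15 of the 22 measured genes. Another 2 members were well above background only in the library labelled Snail, Ccl4 at least 2.32-fold higher and Ccl7 at least 1.11-fold. The list was above the random lists with normexp, at percentile 99.3, and under the stricter filter, at 99.75. Kupffer cell and macrophage markers had a median of 0.19 at percentile 98.9, with Itgax 3.54-fold and Marco 2.83-fold higher and Cd9 4.23-fold lower. MHC class II and dendritic markers had a median of 0.63, above all random lists, with Cd83 2.53-fold, Clec9a 1.97-fold and H2-DMa 1.87-fold higher. Of 12 measured members 1 was at least 2-fold higher, and over the alternatives the median was lowest without a filter, at 0.09.

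Neutrophil markers had a median of 0.13 at percentile 79.2, with the calprotectin genes S100a8 and S100a9 3.96-fold and 2.96-fold higher. Without a filter the neutrophil median was -0.08 at percentile 99.93, against the median of all genes of -0.47. T and NK cell markers had a median of 0.02 at percentile 56.1, with Zap70 4.54-fold lower, and B and plasma cell markers a median of 0.02 at percentile 57.5, with Sdc1 2.41-fold lower and Ms4a1 2.37-fold higher. With bounds these medians were 0.11 and 0.52, and under the stricter filter that of T and NK cell markers was -0.82 at percentile 0.74. Interferon response genes were lower, with 5 of 37 at least 2-fold lower, 0 at least 2-fold higher and a median of -0.43, below all random lists. Zbp1 was 3.10-fold lower, Oasl1 2.94-fold and Bst2 2.64-fold. Complement genes had a median of -0.33 at percentile 3.48, with Cfi 2.08-fold lower; the percentile was 2.45 without shared members and 0.65 among random lists not matched on expression.

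The list of matrix genes lay within the random lists, and stellate cell markers were lower. Of 23 measured fibrosis and matrix genes 2 were at least 2-fold higher and 1 was at least 2-fold lower, with a median of -0.09 at percentile 21.2, and 0.02 with bounds. Ccn2, also called connective tissue growth factor, was 3.15-fold higher, and the collagen gene Col3a1 1.94-fold, while Col1a1 had a log2 difference of 1.32 and the proteoglycan gene Lum was 3.07-fold lower. Acta2, the smooth muscle actin of myofibroblasts, was 1.93-fold higher by its observed signals, which were dim, 14.4 in wild-type liver and 36.1 in the other. Of 18 measured stellate cell and myofibroblast markers 5 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.84, below all random lists; Colec10 was 3.79-fold lower, Angptl6 2.86-fold and Ecm1 2.54-fold. Sinusoidal endothelial markers had a median of 0.07 at percentile 86.9, with Lyve1 3.98-fold and Cd34 2.62-fold higher. TGF-beta response genes had a median of 0.19 at percentile 95.1, with Jun 3.61-fold higher and Inhba 2.92-fold lower; the percentile was 98.15 under the stricter filter and 97.69 without a filter.

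Hepatocyte genes were lower in several functions. All 36 plasma protein genes were measured, 7 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.68, below all random lists. The complement component gene C8b was 24.3-fold lower, the coagulation factor gene F9 12.4-fold, the HDL apolipoprotein gene Apoa1 8.22-fold and Serpina6 2.63-fold. Alb was 1.54-fold lower, a log2 difference of -0.63, but 0.04 under quantile normalization and in the authors' value table. The list's median was -0.30 at percentile 0.020 under quantile normalization, and -0.38 against genes of like signal. Hepatocyte transcription factors had a median of -0.33 at percentile 0.57, with Foxa3 3.52-fold and Klf15 2.96-fold lower and the xenobiotic receptor Nr1i2 2.02-fold higher; without shared members the percentile was 3.24.

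Of 23 measured drug-metabolizing P450 genes 10 were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.90, below all random lists. Cyp2d10 was 13.9-fold and Cyp1a2 5.19-fold lower, against the higher value of Cyp2c55. Of 34 urea cycle and amino acid genes 12 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.75, below all random lists. Mat1a, the liver-type methionine adenosyltransferase, was 10.1-fold lower, Got1 6.79-fold and Agxt 4.02-fold. Wnt targets and pericentral genes had a median of -0.88, below all random lists, with 10 of 21 at least 2-fold lower. Slc13a3 was 8.75-fold lower, Sult5a1 4.34-fold lower and the receptor gene Lgr5 at least 6.83-fold lower, while the Wnt target Axin2 was at least 1.53-fold higher. Periportal genes had a median of -0.42 at percentile 0.65, with Arg1 3.74-fold lower and Sox9 2.92-fold higher; the percentile was 3.69 under quantile normalization and 18.45 without shared members.

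Genes of gluconeogenesis and glycogen had a median of -0.61 at percentile 0.070, with Irs2 5.49-fold and Igfbp1 4.80-fold lower. Glycolysis genes had a median of -0.06 at percentile 46.8, with Pdk1 4.06-fold lower and Hk2 3.63-fold higher, and a median of 0.04 with bounds. Bile acid genes had a median of -0.20 at percentile 9.31, with the sterol 12-alpha-hydroxylase gene Cyp8b1 16.8-fold lower and the drug efflux pump gene Abcb1a 6.95-fold higher; the percentile was 0.80 under the stricter filter and 2.16 without a filter. Conjugation enzymes had a median of -0.05 at percentile 66.5, with the glutathione transferase genes Gsta1 and Gsta2 21.5-fold and 5.83-fold higher and Ugt2b1 7.53-fold lower. NRF2 antioxidant genes had a median of 0.35 at percentile 99.99, with 2 of 19 at least 2-fold higher, Cbr3 at 23.4-fold and Nqo1 at 3.85-fold, and 1 lower, Trib3 at 3.15-fold. Genes of the unfolded protein response had a median of -0.39 at percentile 0.14, with Derl3 27.0-fold and Atf5 2.56-fold lower. Of 26 acute phase genes 12 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -0.55 at percentile 0.030. Serpina3n was 27.5-fold lower beside both metallothioneins.

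Over the 37 lists for the study's question and other liver functions, 7 medians lay above the central 95% of random lists, 15 below it and 15 within it.

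**Figure D3:**
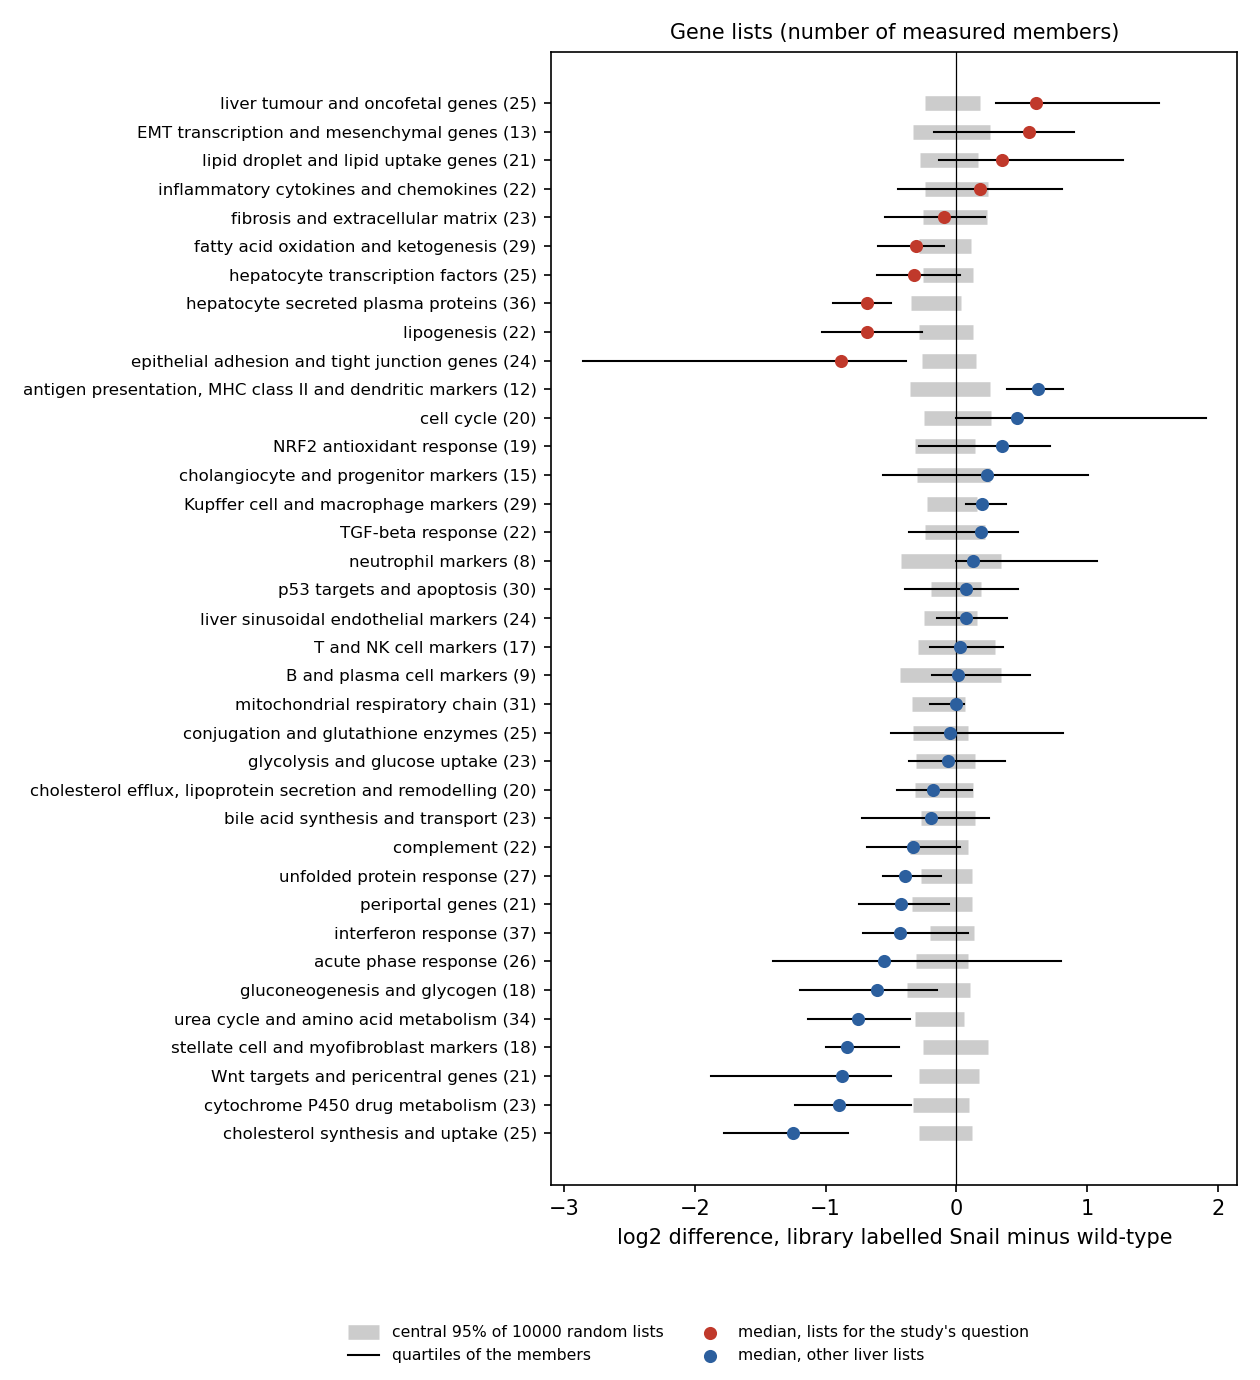
Median log2 difference (x axis, library labelled Snail minus wild-type) of 37 gene lists, with the number of measured members in brackets. Points are medians, black lines span the quartiles of the members and grey bars span the central 95% of 10000 random lists; 7 medians lie above the bars and 15 below.

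The background lists differed as well. Male-biased liver genes had a median of -1.64 and female-biased genes a median of -0.59, both below all random lists, and with bounds -1.55 and -0.64. Beside Cyp4a12a and Cyp4a12b, Elovl3 of the first list was at least 8.32-fold higher, while Slco1a1 and Hsd3b5 were at least 12.3-fold and 9.37-fold lower. Egfr was 13.0-fold and Mup2 10.2-fold lower among the first, and Hamp2 21.4-fold and Sult3a1 9.21-fold lower among the second. Cyp3a44, also female-biased, had the lower bound given above. Clock genes that peak with Dbp had a median of -0.21 at percentile 13.5, with Nr1d1 11.1-fold lower beside Dbp. Of 10 measured, 4 were at least 2-fold lower and 0 at least 2-fold higher, and 2 more, Per2 and Per3, were well above background only in wild-type liver. Clock genes in antiphase had a median of 0.55 at percentile 99.80, with Arntl 1.76-fold higher and Gys2 1.72-fold lower. With bounds the median of the genes peaking with Dbp was -0.52. Their percentile was 0.785 without a filter, and that of the genes in antiphase was 92.0 with normexp. Of 15 adipocyte genes 4 were measured, with a median of 2.502, above all random lists. It rested on Cidec and the adrenergic receptor gene Adrb3, which was 23.0-fold higher; with Slc2a4 at its bound the median was 1.18. Without a filter on dim probes the adipocyte median was -0.47, the difference between the floors of both arrays. Immediate early and stress genes had a median of 0.71, above all random lists. Of 8 measured members 4 were at least 2-fold higher, among them Jun, and 1 was at least 2-fold lower, Egr1 at 5.45-fold. Atf3 was at least 2.24-fold higher, a bound of 1.16 on the log2 scale that was 0.18 with normexp. The median of these genes was -0.47 at percentile 28.2 without a filter, and 0.36 at percentile 97.1 without shared members. Erythroid genes had a median of -0.19 at percentile 15.4, and of the globin genes Hba-a1 differed by -0.19, Hba-a2 by -0.06, Hbb-b2 by -0.13 and Hbb-bt by 0.09, the first pair of which changed sign under quantile normalization, in the authors' value table and against genes of like signal. Pancreatic acinar genes had a median of -0.11 at percentile 29.9, skeletal muscle genes 0.42 at percentile 91.6, but -0.09 with normexp and -0.47 without a filter, and gallbladder and intestinal genes -0.07 at percentile 40.55. With bounds the acinar median was 0.15 and the gallbladder median 0.64. Of mesothelial genes 2 were measured, Cpe at -0.99 and Msln at -0.47. Ribosomal protein genes had a median of 0.14 at percentile 99.98, with 0 of 37 members 2-fold apart, and housekeeping genes a median of -0.03 at percentile 63.4, which was 0.19 under quantile normalization, with Gapdh 1.58-fold and Tfrc 3.23-fold lower. All 8 Y-linked genes were below background on both arrays.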

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

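The setting of each gene against genes of like signal was chosen after seeing the data, and the other alternatives were fixed in advance. No paired analysis was possible because each group had 1 array, and leaving out a replicate or blocking on the slide was not possible either. For the same reason no value here carries a difference between animals, and signals near background limit the folds of genes dim on 1 array.

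The counts of genes at least 2-fold higher and lower were 613 and 980. They were 297 and 572 with normexp, with 290 and 572 genes shared, and 231 and 517 under the stricter filter, which kept 8233 genes. At 1.5-fold they were 1551 and 2245, and at 4-fold 121 and 243. The offset of 50 in normexp shrinks dim differences, and 95 of 235 named values moved by over 1.5-fold with it, against 13 without a filter and at most 1 under any other alternative. No named gene at least 2-fold apart turned its sign. Without a filter the median of all genes was -0.47, the difference between the floors of both arrays.

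The EMT median of 0.55 was 0.30 with normexp and 0.38 against genes of like signal, and it reversed to -0.27 without a filter and -0.015 under the stricter filter. Also reversed was the cell cycle median, to -0.19 under the stricter filter. The adipocyte and immediate early medians went to -0.47 without a filter, the difference between the floors. These 4 lists lay outside the random lists, and 14 lists within them also turned sign under at least 1 alternative, among them cholangiocyte and skeletal muscle genes, both to -0.47 without a filter. Normexp gave -0.75 for junction genes, -0.55 for lipogenesis and 0.49 for tumour genes. Quantile normalization gave -0.57 for lipogenesis, 0.50 for lipid droplet genes, -0.12 for fatty acid oxidation and -0.30 for plasma proteins, and the authors' value table gave -0.58, 0.49, -0.13 and -0.30. Loess gave 0.47 for lipid droplet genes, -0.15 for fatty acid oxidation and -0.46 for plasma proteins, and genes of like signal gave -0.16 and -0.38 for the last 2. Cytokine genes were at -0.47 without a filter and 0.45 under the stricter filter, and matrix genes at -0.41 without a filter. Medians of -0.47 without a filter are the floor difference of members under both floors and reverse no measured difference. The cause of the other moves was not tested. Over the alternatives 7 or 8 lists lay above the random lists and 13 to 17 below.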

Other observations

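The genes in this paragraph and the next were chosen after their values were seen. Imprinted genes were looked at because of H19. Of 30 textbook imprinted genes on the array 16 were measured on both arrays, 6 were at least 2-fold higher and 2 at least 2-fold lower in the library labelled Snail, with a median log2 difference of 0.51. Airn was 4.99-fold higher, Meg3 4.92-fold, Grb10 4.56-fold, Impact 2.54-fold and Kcnq1ot1 2.48-fold, Mirg had a log2 difference of 1.32, and Igf2 and Dio3 were at least 2.97-fold and 1.85-fold higher. Ndn was 1.75-fold lower by its observed signals. Snrpn and Slc38a4 were 2.52-fold and 2.04-fold lower. A further 9 of the genes, among them Dlk1 and Peg3, were below background on both arrays. Over all genes, medians per chromosome were between -0.06 and 0.01, with 2.67% to 5.16% of genes at least 2-fold higher and 4.45% to 8.35% at least 2-fold lower.

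Acute phase genes split within the list. The serum amyloid genes Saa1, Saa2 and Saa3 had log2 differences of 1.40, 1.63 and 2.23, and Lcn2, the neutrophil gelatinase-associated lipocalin gene, 3.16, while Itih4 was at -3.54. The orosomucoid genes Orm1 and Orm2 were at -1.15 and -1.37 and Orm3 at 0.76. All 9 measured genes named Mup, the major urinary proteins, were at least 2-fold lower, with a median of -2.85; their sequences are alike, and whether each probe binds 1 copy alone was not computed.

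Of the tests below, those on adipose tissue, hepatocyte share and sex, and the setting against genes of like signal, were chosen only after the result was seen. With 1 animal per group, an effect of the transgene cannot be separated from any other difference between these animals, and that holds for each pattern.

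Lipid droplet genes were higher in the library labelled Snail, led by Plin4 and Cidec. Adipose tissue in the sample would bring its abundant transcripts, but of Adipoq, Cfd, Retn, Lep and Plin1, 0 of 5 were well above background there, with a highest signal of 9.09. Background correction or normalization does not account for the pattern either, since the lowest median over 5 alternatives was 0.32, at a percentile of at least 99.975. No other explanation was tested for this pattern, and the genotype stays open among them.

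Plasma protein genes of hepatocytes were lower. Markers of other liver cells moved apart, with stellate cell markers at -0.84, macrophage markers at 0.19 and sinusoidal endothelial markers at 0.07. A loss of hepatocytes that raised all other liver cells alike would have raised all of them. A share lost to only some cell types need not, so a lower share of hepatocytes stays open. A trend with brightness is not the whole cause, since the median of -0.68 was -0.46 after loess, still below all random lists, and -0.38 against genes of like signal. Whether the part removed was a trend of the arrays or lower levels of the brightest transcripts was not tested. Lower transcript levels per hepatocyte, for genes such as C8b, F9 and Apoa1, stay open as well, and so does a loss of stellate cell transcripts with them.

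Of genes higher in male than in female liver, Cyp4a12a and Cyp4a12b were at least 448.9-fold and 671.0-fold higher in the library labelled Snail, and Elovl3 at least 8.32-fold, Slco1a1 and Hsd3b5 were at least 12.3-fold and 9.37-fold lower, and the 17 male-biased genes measured on both arrays had a median of -1.64, and -1.55 together with the genes at their bounds. Animals of different sex would differ in Xist and in Y-linked genes, but Xist was well above background on both arrays with a log2 difference of 0.18, and 0 of 8 Y-linked genes were well above background on either. Both arrays thus had the pattern of female liver, Xist without Y-linked genes, although the labels give no sex. Whether both copies or 1 of them was higher cannot be told apart: their probes matched at 23 of 60 positions, few enough to exclude cross-hybridization by the bound set in advance. That bound was judged wrong after the value was seen, since each probe can bind the other transcript away from that copy's own probe, and no transcript sequence was at hand to search. The list of female-biased genes was lower as well, with a median of -0.59. Of its 25 measured members 9 were at least 2-fold lower and 3 at least 2-fold higher, and Cyp3a44, seen in wild-type liver only, was at least 179.0-fold lower. The genotype stays open, as untested.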
